A study of Ixodes scapularis with 4 samples.

How the data were processed

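Gene expression was measured by RNA sequencing in 4 libraries of ISE6 tick cells, 2 labelled WT and 2 labelled subolesin knockdown. Libraries were assigned to groups by their titles. Per the submitters' processing notes, the reads were handled with Bowtie, TopHat, Cufflinks and Cuffdiff, whose versions and settings, with the genome build and annotation, are not given in the sources used here. The deposited table gives 1 mean per group in FPKM for each of 28058 loci. A column description deposited with it calls these means normalized hit counts. They were treated as FPKM because short loci had higher lowest values, as division by length gives: the 10th percentile of loci without a gene ID was 65.0 FPKM under 150 bp and 1.36 FPKM from 500 to 1000 bp. The log2 fold change deposited by the authors is that of the knockdown mean over the WT mean, and it differed from the value recomputed from the means by at most 1.35e-05. The p-value of each locus is the authors' and was deposited without adjustment. The column description names a Wald test for it, but 100% of the values were multiples of 5e-05 (tolerance 1e-06 of a step), as a resampling test gives. The lowest p-value, 5e-05, was shared by 302 loci, which cannot be ranked among themselves.

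The table holds 0 columns of single libraries and no read counts, so no test between libraries was fitted here, libraries of a group were not compared, and the depth per library is unknown. The plan made before the data were examined counted the authors' calls by adjusted p. The table has none, so the Benjamini-Hochberg adjustment was computed here over the 27487 loci with at least 1 FPKM in at least 1 group, and a locus was called at 0.05. Sizes of change were computed as log2((knockdown + 1)/(WT + 1)). Starts are 0-based in the table and are printed 1-based. Spans include introns, and 969 loci share their coordinates with another. The adjustment was tested on simulated p-values for 27487 loci with 200 changed: 18.0%, 57.0% and 91.0% were recovered at shifts of 3, 4 and 5 standard errors, with 1, 3 and 6 false calls, and 0 calls were made with no change. The simulated loci were independent and their p-values exact. The simulation therefore checks the adjustment and does not estimate false calls among the loci called from the authors' p-values.

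Before the data were examined, 28 gene lists and a rule for named genes were fixed. The lists were defined by words in gene descriptions. The files do not pair gene IDs with names or descriptions, and 0 of 11394 gene IDs matched the table of 38656 genes of assembly ASM1692078v2. The lists therefore had 0 matched members and were not tested, and the knockdown of subolesin was not checked. The rule named subolesin, the 8 described genes with the steepest rise and the 8 with the steepest fall among called genes with a finite fold, called list members, and the 3 most abundant genes. Without descriptions, 2 genes with a single gene ID were named in each direction, and the most abundant loci were given by position.

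Classes of gene ID, span and level, neighbouring loci and runs were chosen after the data were examined. Neighbours were adjacent tested loci that do not overlap. Ratios and calls were shuffled 1000 times within class of gene ID and 10 classes of level. Runs joined tested loci, called or not, with gaps of at most 20000 bp and were kept with at least 3 calls in a single direction and 0 in the other. Random lists numbered 10000 and were matched on level in 20 classes. Intervals of medians came from 1000 bootstrap draws over loci, and intervals of shares were exact binomial. Alternatives changed the pseudocount, the filter, the scaling, the threshold and the minimum fold, and, chosen after the data were examined, the loci included, a running median over 501 loci along level, and the counting of near neighbours. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.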

Results

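RNA sequencing was used to ask which transcripts of tick cells differ in abundance when subolesin is knocked down. Subolesin is the tick member of the akirin family, nuclear proteins that take part in the control of transcription. The cells were ISE6, a line derived from embryos of the black-legged tick Ixodes scapularis. The 4 libraries were made from polyA-enriched RNA with a stranded kit, 2 from cells labelled wild type (WT) and 2 from cells labelled subolesin knockdown. The treatment label of all 4 libraries names RNA interference, and whether the WT cells received a control RNA is not given in the sources used here. The deposited table held 1 mean per group for each of 28058 loci on 10901 scaffolds, in FPKM (fragments scaled to transcript length and library size). A locus is a stretch of a scaffold to which transcripts were assigned. Of these loci, 10767 carried a single gene ID, 327 carried several and 16964 carried none. The median was 16.9 FPKM in WT and 16.5 FPKM in knockdown, and the FPKM of all loci summed to 3436081 and 3890991. Read counts and values of single libraries were not used here, so depth is unknown and group means are the authors', without a replicate spread.

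Transcripts changed in both directions with subolesin knockdown. Of 27487 loci with at least 1 FPKM in at least 1 group, 771 (2.80%) differed between knockdown and WT, 446 of them higher in knockdown and 325 lower. The median log2 ratio was 1.23 among loci that rose, a 2.35-fold increase, and -1.11 among loci that fell, a 2.15-fold decrease. Across all tested loci the median log2 ratio was -0.02, with quartiles of -0.41 and 0.36. Ratios are log2 of knockdown over WT after adding 1 FPKM to each, which understates changes at low levels. A locus counted as changed when the authors' p-value, adjusted here by the Benjamini-Hochberg method over the tested loci, was at most 0.05. A ratio of at least 2-fold was measured at 3403 tested loci, of which 547 (16.1%) passed the test, 332 higher and 215 lower. Before adjustment, 4422 of all loci in the table (15.8%) had a p-value below 0.05 in the authors' deposited table, so the adjusted count is not an estimate of how many transcripts differ. At an adjusted threshold of 0.01 the count was 340, with 220 higher and 120 lower. The labels do not say that the libraries of a group came from separate cultures, so the spread between them may be technical. How the authors' test estimated spread is not given in the sources used here.

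**Figure D1:**
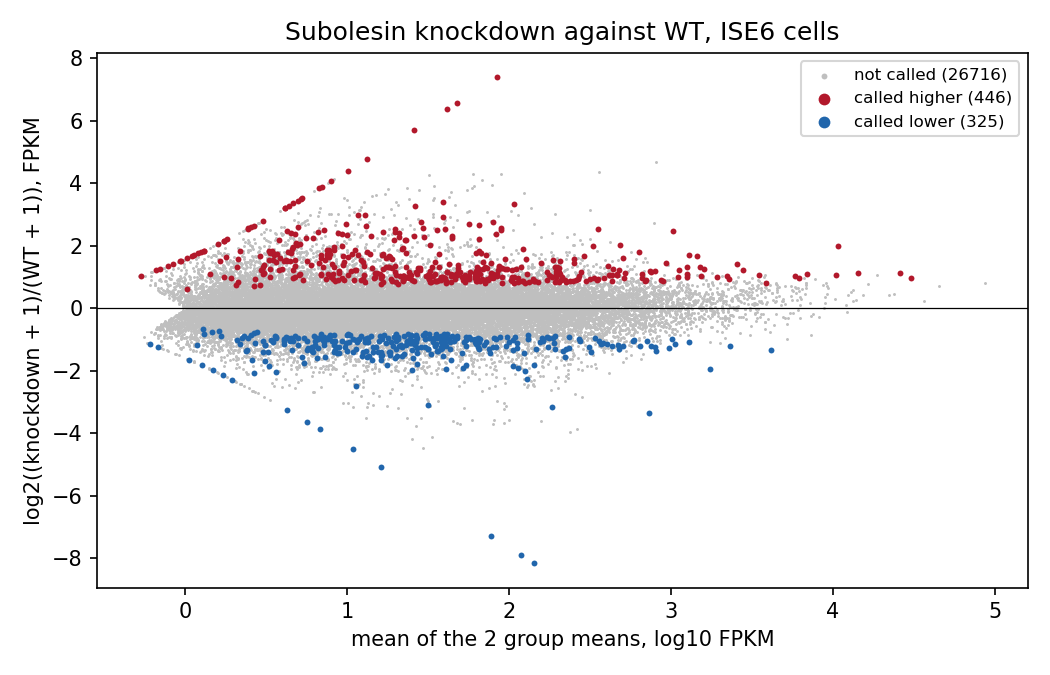
Each point is a tested locus, with the mean of both group means on the x axis (log10 FPKM) and the log2 ratio of knockdown over WT, after adding 1 FPKM to each, on the y axis. The 446 loci that passed the test with higher values in knockdown are red and the 325 with lower values blue; the rising and falling lines of points at the edges are loci listed at 0 in one group.

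Among changed loci with a single gene ID and a value above 0 in both groups, the steepest rises with 1 FPKM added were at ISCW006725 and ISCW001655. ISCW006725, on scaffold DS763375 from 83968 to 102131, had a mean of 4.10 FPKM in WT and 48.5 FPKM in knockdown, a log2 ratio of 3.28. ISCW001655, on scaffold DS636787 from 157403 to 162989, had 1.81 FPKM in WT and 21.5 FPKM in knockdown, a log2 ratio of 3.00, which was 1.96 with 5 FPKM added in place of 1. The steepest falls with 1 FPKM added were at ISCW009296 and ISCW019185. ISCW009296, on scaffold DS831270 from 73768 to 80777, went from 6.41 FPKM in WT to 0.802 FPKM in knockdown, a log2 ratio of -2.04, which was -0.98 with 5 FPKM added in place of 1. ISCW019185, on scaffold DS760728 from 279642 to 311530, was the more abundant transcript, with 202 FPKM in WT and 49.7 FPKM in knockdown and a log2 ratio of -2.00. Its ratio was -1.92 with 5 FPKM added, so the order of these falls depended on the constant. In the authors' deposited table the log2 fold changes of these loci, without an added constant, were 3.56, 3.57, -3.00 and -2.02, with unadjusted p-values of 0.0003, 5e-05, 0.00075 and 5e-05. ISCW006725 and ISCW009296 did not pass at an adjusted threshold of 0.01. The files do not pair gene IDs with gene names, so the function of these genes is not described and the level of subolesin itself was not analysed here.

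Some changed loci were listed at 0 in one group. There were 39 such loci listed at 0 in WT, with a median of 4.90 FPKM and a highest value of 167 FPKM in knockdown. Another 15 were listed at 0 in knockdown, with a median of 8.53 FPKM and a highest value of 284 FPKM in WT. Of these 54 loci, 44 carried no gene ID. In total 134 tested loci were listed at 0 in one group, so a 0 did not by itself give a call. Some loci at 0 in WT with low values in knockdown had the authors' lowest p-value, 5e-05. Some loci just above 0 in WT with similar values in knockdown did not pass. How the authors' test treats a 0 is not given in the sources used here. The 54 calls are therefore less firm than the others, and they are included in the 771. At the other end of the range, the 3 loci with the highest FPKM did not pass the test. They spanned 88, 228 and 7659 bp. Because FPKM is scaled to length, short loci can rank high by it. The locus on DS944702 from 1 to 88, with no gene ID, had 63382 FPKM in WT and 110740 FPKM in knockdown. The locus on DS722680 from 233846 to 234073 had 34065 and 56333 FPKM, and that on DS698118 from 82250 to 89908 had 33530 and 39896 FPKM.

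Among changed loci, the share with a higher value in knockdown varied with the span of the locus. Of 16917 tested loci without a gene ID, 401 changed, 248 higher and 153 lower, so that 61.8% were higher (exact 95% binomial interval 56.9 to 66.6%). Of 10245 tested loci with a single gene ID, 362 changed, 191 higher and 171 lower, a share of 52.8% (47.5 to 58.0%). From 200 to 1000 bp, 69.8% without and 74.3% with a single gene ID were higher, and from 1000 bp on 52.2% and 50.5%. Under 200 bp, 18 of 43 changed loci without a gene ID were higher (41.9%, 27.0 to 57.9%). Of 325 loci with several gene IDs, 8 changed, 7 of them higher. Over all tested loci of a class, changed or not, the median log2 ratio was 0.12 with several gene IDs, at percentile 99.4 of 10000 random lists matched on level. It was -0.01 with a single gene ID, at percentile 99.2, and -0.03 without one, at percentile 0, so that the class as a whole did not share the lean of its changed loci. Without a gene ID the median was -0.12 under 200 bp, -0.01 from 200 to 1000 bp and 0.02 from 1000 bp on. The loci under 200 bp thus lay lowest, and they held 43 of the 401 changed loci. The random lists were drawn from all tested loci and matched on level only, not on gene ID or span. Loci with a single gene ID at 46.1 to 80.9 FPKM already had a median log2 ratio of 0.07. The class with several gene IDs had a median level of 68.5 FPKM. The random lists had medians of 0.027 for several gene IDs, -0.022 for a single one and -0.019 for none. For the 2 large classes the shifts were thus small, and their percentiles are extreme because lists of that size vary little. These 2 classes together make up nearly all loci, so their percentiles are not separate results. Intervals and percentiles describe the loci of these libraries, since loci are not replicates. A change of at least 2-fold passed the test at 218 of 630 loci with a single gene ID (34.6%), at 284 of 1686 loci without one that spanned at least 200 bp (16.8%) and at 39 of 1071 shorter loci without one (3.64%).

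Some loci that fell lay near each other along the scaffolds. Tested loci, changed or not, were joined into a run where the gap between neighbours was at most 20000 bp, so changed loci of a run can lie farther apart than that. There were 7 runs in which at least 3 loci fell and none rose, against a mean of 0.488 and a highest value of 3 in 1000 shuffles of the loci within classes of gene ID and level. Runs in which at least 3 loci rose and none fell numbered 2, within the range of the shuffles, whose mean was 1.31 and highest value 6. At an adjusted threshold of 0.01, 3 runs of falling loci were left, on DS722680, DS760728 and DS953435, against a mean of 0.041 and a highest value of 1 in the shuffles. When the adjustment and the runs were redone on loci with a gene ID only, there was 1 run of falling loci and 1 of rising loci. That falling run need not be among the 7, each of which held at most 2 changed loci with a gene ID. The runs were picked by their changed loci, so the loci that did not pass the test are given apart: of 82 in the 7 runs, 53 had a lower value in knockdown. The run with the most changed loci, on DS760728 from 760373 to 958182, held 25 tested loci, of which 5 fell. Of its 20 others, 15 had a lower value, with a median log2 ratio of -0.38. Across that scaffold 54 loci were tested, 7 fell, ISCW019185 among them, and 0 rose. On DS722680 from 351509 to 389246, 4 of 10 tested loci fell, and the 6 others all had lower values, with a median of -1.56. On DS823764 from 1349 to 120877, 3 of 12 fell, 1 of them a short locus with 1334 FPKM in WT and 129 FPKM in knockdown, and 8 of the 9 others had lower values. On DS962443 from 2852 to 147541, by contrast, 3 of 10 fell and 0 of the 7 others had a lower value. Loci of a run were not joined into transcripts, so these counts are of loci and not of genes. The shuffles moved each locus singly, so pieces of a single transcript counted as separate loci would also exceed them. On DS722680 the 4 loci that fell lay within 3655 bp and carried no gene ID. The excess over the shuffles is therefore not a count of separate changes.

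**Figure D2:**
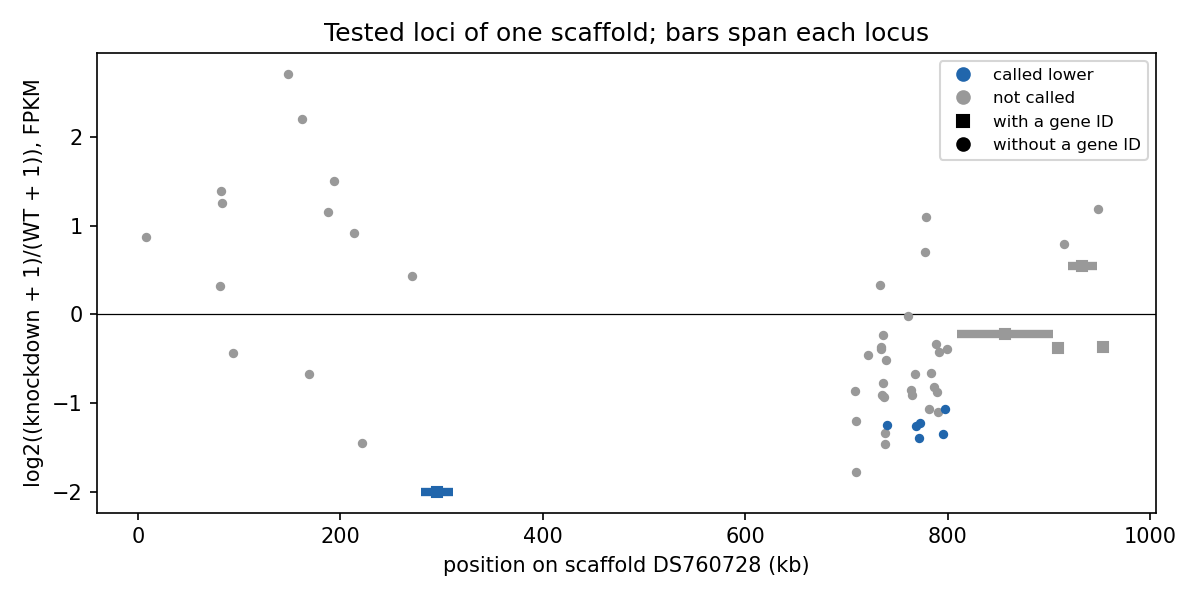
Tested loci along scaffold DS760728, with position in kb on the x axis and the log2 ratio of knockdown over WT, after adding 1 FPKM to each, on the y axis. Bars span each locus, squares carry a gene ID and circles do not, and the 7 loci that fell are blue; 5 of them lie in the run from 760373 to 958182, which also holds loci with higher values.

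Among transcripts with a gene ID, the ratio of knockdown to WT was higher for abundant than for scarce ones. When loci with a single gene ID were ordered by level and divided into 10 classes of equal size, the median log2 ratio was -0.16 in the lowest class and 0.18 in the highest. The difference was 0.33 (95% bootstrap interval over loci 0.28 to 0.39). In the highest class, with at least 187 FPKM, 45 loci rose and 12 fell, and in the lowest class 11 rose and 6 fell. From class 2, with 7 rising and 12 falling, to class 7, with 21 and 27, more loci fell than rose in each. More rose than fell in classes 8 and 9. Loci without a gene ID had medians of -0.12 in their lowest class and 0.06 in their highest, with no steady rise between them: the second class was at 0.01 and the ninth at -0.05. Level and span went together in these loci, with a median of 204 FPKM under 150 bp and 4.33 FPKM from 500 to 1000 bp. Their classes of level therefore also differ in span.

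**Figure D3:**
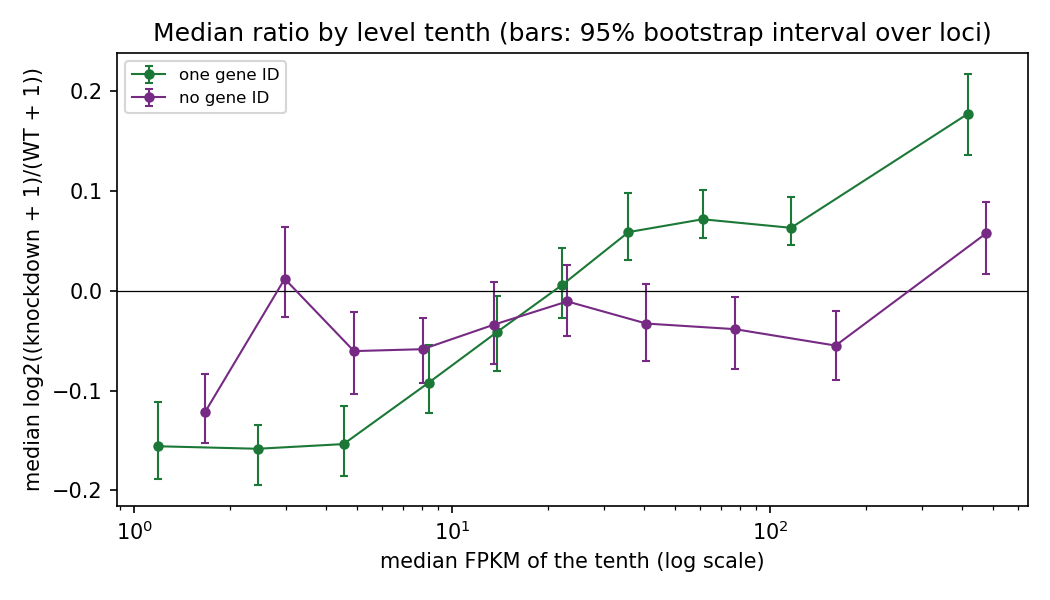
Median log2 ratio of knockdown over WT (y axis, after adding 1 FPKM to each) in 10 classes of level, against the median FPKM of the class (x axis, log scale), for loci with a single gene ID and with none. Bars are 95% bootstrap intervals over loci; medians of loci with a single gene ID range from -0.16 at the lowest levels to 0.18 at the highest.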

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

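Under 11 alternatives, 121 of 151 results kept their direction, call or size, 28 moved, 2 lost their call and 0 called results changed sign. Only the named loci could lose a call or change sign in this count. A count of loci was taken as kept within a fixed fold of the main one, as 547 was for 771. Many of the 121 could not change, since pseudocounts leave the calls and filters leave the ratios of named loci as they were. The median log2 ratio of all tested loci, which is not a called result, went from -0.0194 to 0.00389 with at least 5 FPKM. The count of 771 changed loci was 767 without a filter, 756 with at least 5 FPKM, 547 with a log2 ratio of at least 1, and, under alternatives chosen after the data were examined, 793 without loci under 200 bp and 739 with near neighbours counted once. A threshold of 0.01 left 340 changed loci, 220 higher and 120 lower, 333 of them at least 2-fold apart, and ended the calls of ISCW006725 and ISCW009296. Restriction to loci with a gene ID, also chosen afterwards, tested fewer loci and gave 430 changed, 227 higher and 203 lower, 237 at least 2-fold apart. With a minimum log2 ratio of 1, 215 loci were lower, and a pseudocount of 5, which shrinks ratios, left 336 changed loci at least 2-fold apart. Pseudocounts and scaling do not enter the p-values, so calls could not depend on them. Leaving out each library, other tests between libraries and tests on counts gave no value because the table holds group means, and alternatives for subolesin and for gene lists gave none because IDs were not paired with names. Adjustment over all loci with a p-value is the alternative without a filter. No paired analysis was possible because the groups share no replicate numbers. Unknown depth limits how firmly low loci can be read.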

Other observations

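The patterns here were noticed in the data and tested on the same data. The tests of locus span, of the pseudocount and of low level were written down before their results were seen, and the tests of library differences, transcript pieces, base composition, a shift of all loci and loci without a gene ID after.

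Neighbouring loci had similar ratios. Across 5010 pairs under 1000 bp apart, the ratios had a Pearson correlation of 0.49 over loci, which are not independent replicates, against a highest value of 0.047 in 1000 shuffles. It was 0.57 over 2911 pairs without gene IDs, 0.30 over 1074 pairs where only one locus had an ID, and 0.17 over 956 pairs of different gene IDs. The highest shuffle of the last was 0.11. Of the 5010 pairs, 32 were called in the same direction and 0 in opposite ones, with 14 in the same direction at a threshold of 0.01 and 5 among loci with a gene ID only. Pieces of a single transcript counted as separate loci may account for near pairs, and this was not separated from other sources. A test assumed that such pieces leave pairs of different gene IDs at least 20000 bp apart uncorrelated. It cannot decide, because a transcript split between gene IDs was not excluded at that distance. In it, 637 such pairs had a Spearman correlation of 0.15, above the highest shuffle at 0.13. That margin is small, and the Pearson correlation of the same pairs, 0.15, was level with its highest shuffle, 0.15. Shared base composition cannot be told apart from regulation of neighbouring genes because 0 tested loci had a sequence here to measure it on.

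The rise of the ratio with level among loci with a single gene ID, 0.33 between the highest and lowest of 10 classes, was set against technical sources. Locus span as the whole source is argued against by a gap that was still 0.26 in the span class where it was smallest. The size of the gap depended on the pseudocount, with 0.234 at 5 and 0.436 at 0.1, and it was 0.421 with at least 5 FPKM. Without a pseudocount, over loci with a value in both groups, the gap was 0.46. An added constant keeps the sign of a ratio and shrinks it most at low levels, and the lowest class had a negative median. A wider gap without the constant was therefore implied. It shows that the constant narrowed the gap, and it does not weigh other sources. Subtracting the running median along level left 0.093, as its construction implies. A difference between the libraries other than the knockdown may give the same trend and cannot be told apart from an effect of the knockdown, because 0 columns of single libraries could be compared within a group.

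Changed loci of 200 to 1000 bp were mostly higher in knockdown, 197 against 83 (70.4%, exact 95% interval 64.6 to 75.6%), while those of at least 1000 bp were 229 higher and 215 lower (51.6%), and at a threshold of 0.01 the shares were 73.7% and 58.7%. Changed loci under 200 bp had no such lean, with 20 higher and 27 lower (42.6%, 28.3 to 57.8%). Over all 4954 tested loci under 200 bp the median log2 ratio was -0.109. With 47 changed loci in a class that lay lower, they cannot show whether the lean extends to short loci in general. A common shift of all loci of 200 to 1000 bp is argued against by their median log2 ratio of -0.0102, which does not weigh changes limited to some of them. Low level in FPKM is argued against by a share of 67.9% in the more abundant part of the changed loci of 200 to 1000 bp. FPKM is scaled to length and read counts were not available, so that share does not weigh low read counts. A source limited to loci without a gene ID is argued against by 74.3% among the 35 with a single gene ID. A response of transcripts of this span to the knockdown, and library differences that act on them, may each give this lean, and neither was tested.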
